A study of Mus musculus with 6 samples.

How the data were processed

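Gene counts from 6 libraries of CMT93 spheroids, 3 with vehicle and 3 with 200 µM palmitate, were analysed. Libraries were made from polyadenylated RNA with a stranded kit, per the labels' protocols. The authors used FastQC 0.11.8, STAR 2.6.1, HTSeq and DESeq2 1.34.0 with mouse genome build mm39, per the submitters' processing notes, where HTSeq has no version. The count table holds raw counts for 23399 genes as deposited, with gene symbols of the Gencode release that the authors' column description names. Whether counting used strand is not given in the sources used here. The authors' deposited gene table gives a log2 fold change, a p-value and a q-value from DESeq2, and a score that is the signed −log10 of the p-value, per the column description. Whether those fold changes were shrunk is not given in the sources used here, and 25.2% of its genes have a q-value of exactly 1. The authors' deposited gene set table gives enrichment scores, p-values and q-values from fgsea, per the column description. The reference at hand was of an earlier build, so no positions are given.

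Groups were taken from the sample labels. Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest, two-sided) after TMM normalization and filterByExpr, which uses a minimum count of 10, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. This left 14987 genes. CPM values are TMM-normalised, and the standard error of a log2 fold change is its size divided by the root of its quasi-likelihood F. Gene sets were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, for sets of 5 to 500 tested genes. Of 28 gene lists fixed before the data were examined, 25 had enough tested members; the 3 lists of other cell types are given as values. The lists and the design were fixed then, and so was the rule for named genes: the 10 greatest rises and 10 greatest falls among called genes of at least 1 CPM whose groups do not overlap, up to 4 called members per list by smallest p, a fixed panel of metabolic, stress and epithelial genes, and up to 3 called members of each of up to 6 called metabolic sets. Symbols without a proper gene name were left out of the first part. In comparing 2 libraries of a group, genes with at least 20 summed counts were used. The chi-square over its degrees of freedom was at most 1.38 in the 6 pairs and above counting noise in each, so no library was taken for a copy of another.

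The tests were tried on simulated counts for this comparison, with known changes in a seeded set of real genes. In a step run on 14812 genes, edgeR recovered 61.2% of genes changed 1.2-fold, 82.0% at 1.5-fold, 89.8% at 2-fold and 98.0% at 3-fold, with 9 false calls. The 49 or 50 genes changed at each fold were far fewer than the 7915 called in the data. Camera called a list shifted 1.3-fold, with the preset and with the estimated correlation. With the preset correlation it called 0 of 24 other lists. Simulated genes varied independently of one another, so this could not test camera on correlated genes. No gene outside the shifted list was changed in that step, whereas 7915 genes were called in the data. The shift was also larger than the median change of most called lists. Alternatives were median-of-ratios size factors, no count filter, DESeq2 1.42.0, limma-voom, glmTreat against a 1.2-fold change, the replicate number as a block, an estimated correlation, and leaving out each library. Thinning every library to the shallowest total was added after the data were seen. GC content and length were taken by Ensembl identifier from transcripts of the earlier annotation for 96.4% of tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. With 18.9 to 22.9 M counts per library, relative counting error is larger for genes near 1 CPM than for abundant genes. Some mitochondrially encoded genes were not analysed here.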

Results

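Polyadenylated RNA was sequenced from spheroids of CMT93, an established mouse colorectal carcinoma cell line grown here on soft agar with a low amount of Matrigel. Palmitate, a saturated fatty acid, was given bound to albumin at 200 µM to 3 samples, and the other 3 received the ethanol and albumin vehicle. Each treatment lasted 1 week in monolayer and then 5 days in spheroid culture before RNA was taken. The libraries held 18.9, 21.9 and 21.6 M counts with vehicle and 22.5, 22.7 and 22.9 M with palmitate, so every palmitate library was deeper than every vehicle library. The labels number the samples of a group but do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The variance between 2 libraries of a group was at most 1.38 times that of counting alone, and the common biological coefficient of variation was 1.28%. The comparison asks which transcripts differ between spheroids that were grown with and without palmitate. The series as a whole concerns liver metastases of colorectal cancer in steatosis.

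Spheroids grown with palmitate had more message for Cpt1a, Plin2 and Angptl4, genes that handle fatty acids, and slightly more for the glycolysis gene Ldha, the respiration gene Cox4i1 and the proliferation marker Mki67. They had less for the lipoprotein gene Apob, the goblet cell regulator Spdef, the matrix gene Sparc and the inflammatory genes Tnf and Ccl2. Most differences were small and a few were large. Of 14987 tested genes, 7915 were called at an adjusted p under 0.05 (edgeR quasi-likelihood test, two-sided), 4110 higher and 3805 lower with palmitate. The median called gene differed 1.19-fold, and 676 called genes differed at least 2-fold, 253 higher and 423 lower. The first principal component of log2 CPM held 70.9% of the variance and separated the groups. All 3 libraries of one group lay above all 3 of the other for 57.8% of tested genes, against 10% by chance. Against a minimum fold of 1.2, glmTreat called 2275 genes, 968 higher and 1307 lower.

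**Figure D1:**
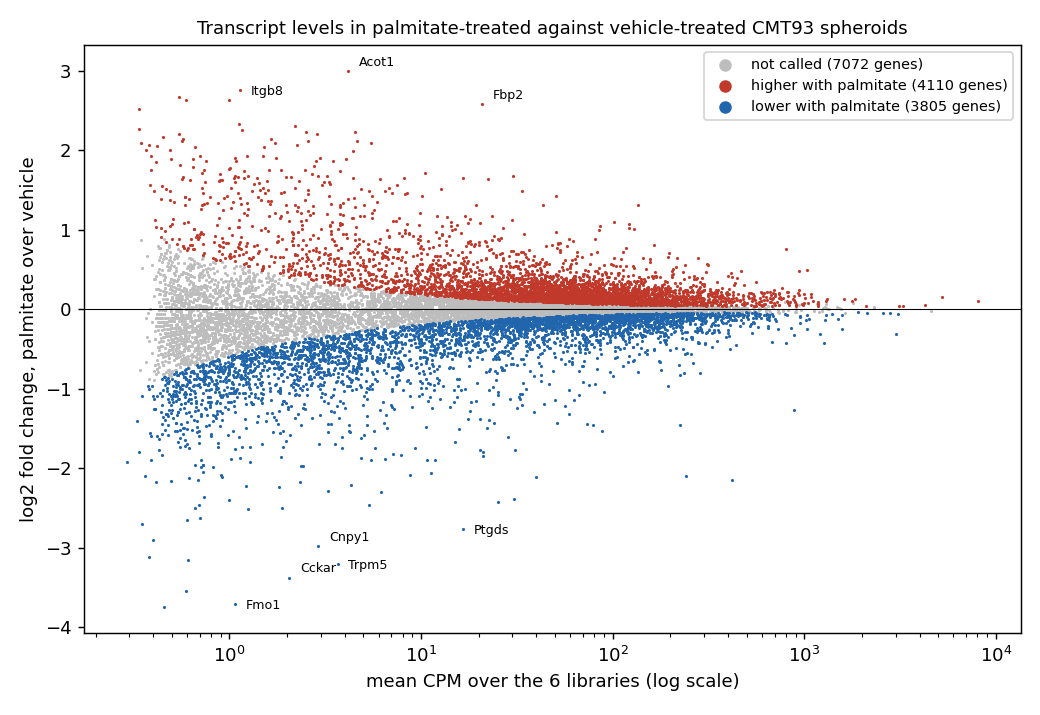
Each point is 1 of 14987 tested genes, with its mean CPM over the 6 libraries (log axis) and its log2 fold change of palmitate over vehicle. Red points are the 4110 genes called higher and blue points the 3805 called lower. Most called genes lie close to 0.

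Among genes of at least 1 CPM on average, the greatest rise was in Acot1 (ENSMUSG00000072949.7), a cytosolic acyl-CoA thioesterase, from 0.922 ± 0.0695 CPM with vehicle to 7.41 ± 0.427 CPM with palmitate (SD, n = 3 libraries each; log2 fold change 2.99, SE 0.158, adjusted p = 6.01e-30, edgeR). Its near-identical relatives can share reads, so this value is uncertain. Fbp2 (ENSMUSG00000021456.9), the muscle form of fructose bisphosphatase in gluconeogenesis, rose from 5.94 ± 0.232 CPM with vehicle to 35.5 ± 0.617 CPM with palmitate (SD, n = 3 libraries each; log2 fold change 2.58, SE 0.0665, adjusted p = 5.69e-52, edgeR). The integrin subunits Itgb8 and Itga7 rose by 2.76 and 2.31 on the log2 scale, from 0.279 ± 0.157 and 0.728 ± 0.132 CPM. The other genes of the 10 with the greatest rise were Tmem229b (2.34), Pwwp3b (2.25), Tdrkh (2.24), Rassf10 (2.23), Artn (2.20) and Kcnk6 (2.14), given with log2 fold changes. Artn encodes artemin, a ligand of the GDNF family, and Kcnk6 a potassium channel. The greatest fall was in Fmo1 (ENSMUSG00000040181.15), a flavin-containing monooxygenase, from 2.00 ± 0.107 CPM with vehicle to 0.148 ± 0.0676 CPM with palmitate (SD, n = 3 libraries each; log2 fold change -3.70, SE 0.329, adjusted p = 4.38e-17, edgeR). The cholecystokinin receptor gene Cckar fell from 3.73 ± 0.418 CPM with vehicle to 0.355 ± 0.132 CPM with palmitate (SD, n = 3 libraries each; log2 fold change -3.38, SE 0.236, adjusted p = 1.48e-22, edgeR). Trpm5, a cation channel of taste and tuft cells, fell from 6.63 ± 0.803 CPM with vehicle to 0.710 ± 0.113 CPM with palmitate (SD, n = 3 libraries each; log2 fold change -3.21, SE 0.175, adjusted p = 4.65e-29, edgeR). Among more abundant genes, Sptssb, a small subunit of serine palmitoyltransferase, fell from 51.4 ± 3.39 CPM with vehicle to 9.82 ± 0.583 CPM with palmitate (SD, n = 3 libraries each; log2 fold change -2.39, SE 0.0569, adjusted p = 7.61e-53, edgeR), and the colipase gene Clps fell from 42.7 ± 2.45 to 7.93 ± 0.344 CPM. The remaining genes of the 10 with the greatest fall were Cnpy1 (-2.98), Ptgds (-2.76), Gbp3 (-2.51), Tat (-2.50) and Creb3l1 (-2.46). Ptgds encodes a prostaglandin D synthase and Gbp3 is one of a family of related GTPases that can share reads.

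Most tested genes that peroxisome proliferator-activated receptors switch on when fatty acids are abundant rose. In this list 14 of 19 tested members were higher, 1 lower and 4 not past the threshold (16 called when adjusted over the list alone), with a median log2 fold change of 0.55 (camera adjusted p = 5.46e-06, adjusted p = 0.0670 with an estimated correlation). Cpt1a, which admits long-chain fatty acids to mitochondria, rose from 218 ± 3.48 CPM with vehicle to 342 ± 2.38 CPM with palmitate (SD, n = 3 libraries each; log2 fold change 0.65, SE 0.0193, adjusted p = 1.63e-47, edgeR). Plin2, a lipid droplet coat protein, rose from 175 ± 3.99 to 253 ± 4.99 CPM, and Angptl4, an inhibitor of lipoprotein lipase, from 14.4 ± 0.634 to 32.7 ± 1.64 CPM. The log2 fold changes of Ucp2 (0.55), Acadl (0.56) and Pdk4 (0.70) were also positive and called. Cd36 was not analysed here.

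Other lipid lists were mixed. For fatty acid oxidation beyond those targets, 7 of 24 tested members were higher, 10 lower and 7 not past the threshold (17 called when adjusted over the list alone), and the list was not called (camera adjusted p = 0.544). Acsl1, an acyl-CoA synthetase, rose by 0.68 on the log2 scale, Etfdh by 0.39 and the peroxisomal enzyme gene Decr2 by 0.59. For fatty acid synthesis and desaturation, 10 of 21 tested members were higher, 5 lower and 6 not past the threshold (15 called when adjusted over the list alone, camera adjusted p = 0.506). Its median log2 fold change was 0.06, its mean -0.01 and its camera direction Up. In it Acacb rose from 9.83 ± 0.410 to 17.2 ± 0.600 CPM, and Me1 (0.24), Acly (0.19), Scd1 (0.16) and Fasn (0.06) had small positive log2 fold changes that were called, while Hacd3 fell (-0.25). Scd2 had a log2 fold change of 0.04, whose call was lost without vehicle replicate 3 or palmitate replicate 1. For triglyceride synthesis and lipid droplets, 11 of 27 tested members were higher, 7 lower and 9 not past the threshold (18 called when adjusted over the list alone, camera adjusted p = 0.544). Apob, the structural protein of triglyceride-rich lipoproteins, fell from 1249 ± 28.5 CPM with vehicle to 519 ± 15.6 CPM with palmitate (SD, n = 3 libraries each; log2 fold change -1.27, SE 0.0174, adjusted p = 3.52e-56, edgeR), and Soat1 fell (-0.29), whereas Dgat2 (0.84) and Acsl4 (0.48) rose. For cholesterol synthesis and uptake, 8 of 25 tested members were higher, 10 lower and 7 not past the threshold (19 called when adjusted over the list alone, camera adjusted p = 0.544), and the values were small: Hmgcs1 (-0.19) and Lss (-0.24) fell and Cyp51 rose (0.12).

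**Figure D2:**
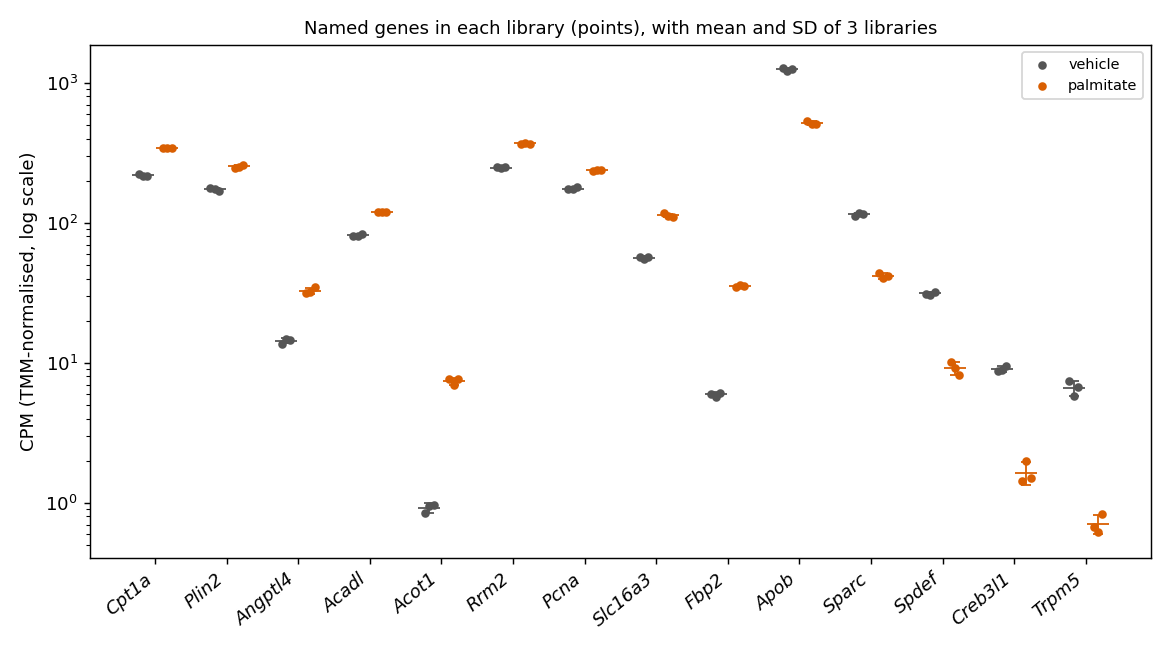
CPM on a log axis for 14 named genes, with each point 1 library, and horizontal ticks and bars the mean and SD of 3 libraries per group. For every gene drawn, the 3 palmitate libraries lie on one side of the 3 vehicle libraries. Cpt1a, Rrm2 and Slc16a3 are among those higher with palmitate and Apob, Spdef and Trpm5 among those lower.

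Genes of carbon metabolism and respiration were mostly higher. In the glycolysis and hypoxia list, 17 of 29 tested members were higher, 4 lower and 8 not past the threshold (21 called when adjusted over the list alone, camera adjusted p = 0.00766, adjusted p = 0.235 with an estimated correlation). The lactate exporter gene Slc16a3 rose from 56.5 ± 1.21 CPM with vehicle to 113 ± 3.50 CPM with palmitate (SD, n = 3 libraries each; log2 fold change 1.00, SE 0.0313, adjusted p = 8.96e-46, edgeR), and Ldha (0.26), Pfkp (0.48) and Aldoa (0.22) rose less. Vegfa, a hypoxia target and vascular growth factor gene, had a log2 fold change of 0.05 (adjusted p = 0.161, edgeR) and was not called. For nuclear genes of oxidative phosphorylation, 20 of 34 tested members were higher, 3 lower and 11 not past the threshold (24 called when adjusted over the list alone, camera adjusted p = 0.00843, adjusted p = 0.178 with an estimated correlation). Those with the smallest p were Cox4i1 (0.20), Atp5b (0.14), Cox5b (0.27) and Ndufs3 (0.35). For the tricarboxylic acid cycle, 13 of 22 tested members were higher, 1 lower and 8 not past the threshold (14 called when adjusted over the list alone, camera adjusted p = 0.0163, adjusted p = 0.178 with an estimated correlation). Idh3b and Idh3a, subunits of isocitrate dehydrogenase, rose from 119 ± 1.74 to 157 ± 1.44 CPM and from 126 ± 3.88 to 164 ± 4.44 CPM, and Mdh1 (0.34) and Dlst (0.24) also rose.

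Most tested genes of dividing cells rose, by small amounts. In the cell cycle and DNA replication list, 25 of 34 tested members were higher, 1 lower and 8 not past the threshold (26 called when adjusted over the list alone), with a median log2 fold change of 0.17 (camera adjusted p = 2.43e-06, adjusted p = 0.0670 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 248 ± 3.30 CPM with vehicle to 369 ± 4.88 CPM with palmitate (SD, n = 3 libraries each; log2 fold change 0.57, SE 0.0188, adjusted p = 3.82e-44, edgeR), and the replication clamp gene Pcna rose from 176 ± 3.71 to 238 ± 1.56 CPM. Mcm5, Top2a and the proliferation marker Mki67 rose by 0.31, 0.25 and 0.15 on the log2 scale. Replication histones, whose messages mostly lack a poly(A) tail, went the other way: 0 of 11 tested members were higher, 5 lower and 6 not past the threshold (1 called when adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0327, adjusted p = 0.214 with an estimated correlation). The call was also lost after all libraries were thinned to the shallowest (adjusted p = 0.0582, camera). Most were low genes. H1f2 had 17.5 ± 1.26 CPM with vehicle and a log2 fold change of -0.19, and its call, like those of H4c4 (-0.41), H2ac6 (-0.53) and H3c3 (-0.47), was lost with DESeq2 and without any of several single libraries. Histone copies can share reads. For MYC targets and ribosome assembly, 13 of 25 tested members were higher, 2 lower and 10 not past the threshold (15 called when adjusted over the list alone, camera adjusted p = 0.0123, adjusted p = 0.178 with an estimated correlation). Tfrc, the transferrin receptor gene, rose from 216 ± 0.598 to 285 ± 5.80 CPM, and Nop56 (0.38), Pes1 (0.25) and Npm1 (0.13) rose too. Myc itself had a log2 fold change of -0.09, and its call was lost with DESeq2, with no count filter and without vehicle replicate 1 or 3 or palmitate replicate 2 or 3.

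Stress genes such as Chac1 and Hmox1 rose. For the unfolded protein and integrated stress response, 15 of 32 tested members were higher, 11 lower and 6 not past the threshold (26 called when adjusted over the list alone), and the list was not called (camera adjusted p = 0.544). Chac1, a glutathione-degrading target of ATF4, rose from 9.64 ± 0.889 CPM with vehicle to 19.3 ± 0.880 CPM with palmitate (SD, n = 3 libraries each; log2 fold change 1.00, SE 0.0703, adjusted p = 2.62e-22, edgeR), and Atf4 rose (0.23), while Vldlr (-0.24) and Dnajc3 (-0.25) fell. The chaperone gene Hspa5 had a log2 fold change of 0.05, not called without palmitate replicate 1, and Ddit3 of 0.22, not called with DESeq2 or without vehicle replicate 1 or 2 or palmitate replicate 2. For oxidative stress and ferroptosis defence, 13 of 22 tested members were higher, 3 lower and 6 not past the threshold (16 called when adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.293 with an estimated correlation). Hmox1, heme oxygenase, rose from 39.5 ± 1.28 to 66.4 ± 1.21 CPM and Srxn1 (0.40) and Gsr (0.32) rose, while Gsta4 fell (-0.41). A list of immediate early and heat shock genes, which respond to handling as well as to signals, moved in the same direction. In it 13 of 18 tested members were higher, 0 lower and 5 not past the threshold (14 called when adjusted over the list alone, camera adjusted p = 0.00487, adjusted p = 0.171 with an estimated correlation). Those higher included the immediate early genes Dusp1 (0.50) and Jun (0.26) and the heat shock genes Hsph1 (0.19) and Hspa1b (0.79). Hspa1b has a near-identical copy and is uncertain. For apoptosis and p53 targets, 11 of 23 tested members were higher, 6 lower and 6 not past the threshold (17 called when adjusted over the list alone, camera adjusted p = 0.544). In this list Cdkn1a (0.71) and Ccng1 (0.40) rose, while Plk2 fell (-0.64).

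Markers of epithelial state moved in both directions within each list. For junctions and keratins, 7 of 25 tested members were higher, 11 lower and 7 not past the threshold (19 called when adjusted over the list alone, camera adjusted p = 0.310). Krt18 fell from 1445 ± 21.4 to 1079 ± 7.71 CPM and Krt8 (-0.24) and Tjp1 (-0.27) fell, whereas the claudin gene Cldn3 rose from 3.92 ± 0.367 CPM with vehicle to 12.4 ± 0.661 CPM with palmitate (SD, n = 3 libraries each; log2 fold change 1.66, SE 0.0974, adjusted p = 5.67e-27, edgeR). Cdh1, which encodes E-cadherin, had a log2 fold change of -0.05, whose call was lost without palmitate replicate 3. For mesenchymal transition genes, 8 of 23 tested members were higher, 9 lower and 6 not past the threshold (17 called when adjusted over the list alone, camera adjusted p = 0.763). Their median was -0.03 and camera direction Down, but their mean was 0.02. Sparc, a secreted matrix protein, fell from 115 ± 2.93 CPM with vehicle to 41.9 ± 1.92 CPM with palmitate (SD, n = 3 libraries each; log2 fold change -1.46, SE 0.0335, adjusted p = 1.03e-55, edgeR), and Fn1 (-0.31), Vim (-0.23) and Runx1 (-0.51) fell, while Tgfbi rose from 10.8 ± 1.04 to 33.8 ± 1.18 CPM and Cd44 rose (0.49). For stem cell and WNT targets, 8 of 17 tested members were higher, 8 lower and 1 not past the threshold (16 called when adjusted over the list alone, camera adjusted p = 0.915). Their median was 0.05, but their mean was -0.11 and camera direction Down. The WNT feedback gene Axin2 rose from 168 ± 3.06 to 264 ± 2.68 CPM and the stem cell marker Lgr5 rose (0.19), while Lrig1 (-0.66) and Apcdd1 (-0.80) fell. For intestinal differentiation, 3 of 9 tested members were higher, 4 lower and 2 not past the threshold (7 called when adjusted over the list alone, camera adjusted p = 0.486). Spdef, a regulator of goblet cells, fell from 31.3 ± 0.869 CPM with vehicle to 9.16 ± 0.940 CPM with palmitate (SD, n = 3 libraries each; log2 fold change -1.77, SE 0.0630, adjusted p = 8.15e-42, edgeR), and the mucus protein gene Fcgbp fell from 29.3 ± 1.61 to 11.3 ± 0.960 CPM. The tuft cell markers parted, with Trpm5 lower and Dclk1 higher, from 12.8 ± 0.710 to 23.3 ± 0.266 CPM.

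For actin nucleation and motility, 10 of 31 tested members were higher, 13 lower and 8 not past the threshold (25 called when adjusted over the list alone, camera adjusted p = 0.915). The list was Down by camera and Up by fry, which tests the members alone. The small GTPase gene Rhob rose from 32.7 ± 0.0499 to 57.0 ± 1.28 CPM, and of the ARP2/3 complex Arpc1b rose (0.21), Arpc3 rose (0.14) and Arpc5 fell (-0.41). Pfn1 rose (0.13). For extracellular matrix and angiogenic factors, 6 of 25 tested members were higher, 11 lower and 8 not past the threshold (17 called when adjusted over the list alone, camera adjusted p = 0.544). Pdgfa, a growth factor gene, fell from 362 ± 3.98 CPM with vehicle to 208 ± 4.17 CPM with palmitate (SD, n = 3 libraries each; log2 fold change -0.80, SE 0.0194, adjusted p = 9.67e-54, edgeR), and Lamb3 (-0.31) and Lama5 (-0.17) fell, while Col4a2, a basement membrane collagen gene, rose (0.43).

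Among inflammatory genes driven by NF-kB, more were lower than higher. In this list 4 of 23 tested members were higher, 12 lower and 7 not past the threshold (18 called when adjusted over the list alone), with a median log2 fold change of -0.20 (camera adjusted p = 0.0272, adjusted p = 0.320 with an estimated correlation). With no count filter its camera adjusted p was 0.0704. Tnf fell from 13.8 ± 0.253 to 8.27 ± 0.493 CPM, Ccl2 from 31.3 ± 0.677 to 21.8 ± 1.81 CPM and Cxcl5 from 127 ± 3.27 to 100 ± 0.446 CPM, and the subunit gene Nfkb2 fell (-0.29). The interferon list was split: 8 of 26 tested members were higher, 8 lower and 10 not past the threshold (16 called when adjusted over the list alone, camera adjusted p = 0.915). Its median was 0.11 and camera direction Up, but its mean was -0.03 and fry direction Down. The class I histocompatibility genes H2-K1 and H2-D1 rose by 1.02 and 0.51 on the log2 scale, whereas Gbp2 and Usp18 changed by -1.74 and -0.79. H2-K1, H2-D1 and Gbp2 have close relatives that can share reads.

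**Figure D3:**
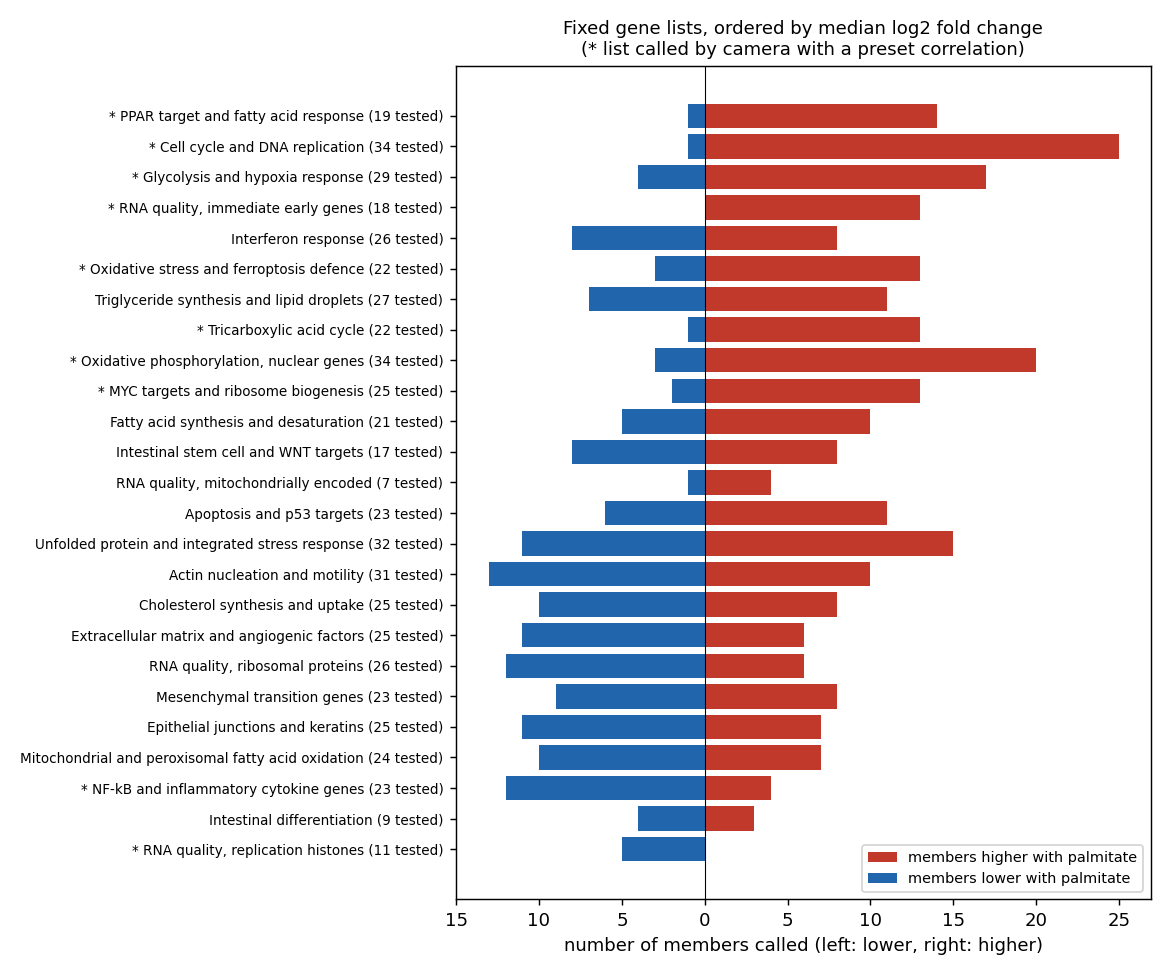
Numbers of members called higher (right, red) and lower (left, blue) with palmitate in each of 25 tested gene lists, ordered by median log2 fold change, with the number of tested members in brackets. An asterisk marks the 10 lists called by camera with a preset correlation. None was called with an estimated correlation.

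Over the 25 fixed lists tested, camera with a preset correlation called 10, of which 8 were higher and 2 lower. With an estimated correlation it called 0, the lowest adjusted p was 0.0670, and 6 lists had an unadjusted p under 0.05. By fry, 21 lists were called. The 10 lists called with the preset correlation included the replication histones (lower) and the immediate early genes (higher), which were fixed as checks of RNA quality. The other such checks, ribosomal protein and mitochondrially encoded genes, were not called by camera. Markers of other cell types stayed low. Of 4 tested fibroblast and endothelial markers, 3 were lower and 1 was not called. Of these, Acta2 (-1.46), Des (-0.93) and Cdh5 (-0.60) fell, from 3.48 ± 0.286, 2.87 ± 0.526 and 2.21 ± 0.337 CPM, and the call of Cdh5 was lost with DESeq2 and without vehicle replicate 3. Of 4 tested blood and immune markers, 1 was higher, 2 lower and 1 not called. In this list Cd68 rose from 7.14 ± 0.739 to 9.66 ± 0.622 CPM and Ptprc (-1.62) and Hba-a1 (-1.27) fell from under 1 CPM. Of liver and fat cell markers only Tat was tested, and it fell. Ribosomal protein genes were mixed: 6 of 26 tested members were higher, 12 lower and 8 not past the threshold (19 called when adjusted over the list alone, camera adjusted p = 0.544), with Rps29 (0.16), Rpl23 (0.14) and Rpl13 (0.10) higher and Rps12 lower (-0.11). Their processed copies can share reads. For mitochondrially encoded genes, 4 of 7 tested members were higher, 1 lower and 2 not past the threshold (5 called when adjusted over the list alone, camera adjusted p = 0.397), with mt-Cytb (0.16) and mt-Co1 (0.11) higher and mt-Nd5 lower (-0.06), the last not called by limma-voom. mt-Nd1 had a log2 fold change of 0.04 and lost its call with DESeq2, with limma-voom, after thinning and without any of vehicle replicate 1 and palmitate replicates 1 and 3. These genes took 2.27% to 2.31% of counts with vehicle and 2.35% to 2.41% with palmitate.

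Fbp2, Idh3b and Uqcr10, genes of central carbon metabolism and respiration, were higher with palmitate. Aldh3a1 and Gsta2, genes of drug metabolism, were lower. The gene sets used were those that the authors of the series chose. Of 87 sets tested, camera called 11, 8 higher and 3 lower with palmitate. With an estimated correlation it called 0, with 8 sets at an unadjusted p under 0.05, and fry called 67. For oxidative phosphorylation, 57 of 106 tested genes were higher and 13 lower (camera adjusted p = 0.00774, adjusted p = 0.393 with an estimated correlation). Uqcr10 rose (0.40) but the proton pump subunits Atp6v0a4 (-0.94) and Atp6v1a (-0.27) fell. For carbon metabolism, 52 of 98 tested genes were higher and 15 lower (camera adjusted p = 0.00774, adjusted p = 0.393 with an estimated correlation), with Fbp2, Idh3b and Esd (0.47) higher. For fructose and mannose metabolism, 14 of 29 tested genes were higher and 4 lower (camera adjusted p = 0.0155, adjusted p = 0.393 with an estimated correlation), including Akr1b8 (0.81) and Pmm1 (0.79). For the citrate cycle, 18 of 28 tested genes were higher and 3 lower (camera adjusted p = 0.0155, adjusted p = 0.393 with an estimated correlation), and for glycolysis and gluconeogenesis, 26 of 46 tested genes were higher and 9 lower (camera adjusted p = 0.0293, adjusted p = 0.393 with an estimated correlation). Drug metabolism by cytochrome P450 was called lower: 4 of 38 tested genes were higher and 21 lower (camera adjusted p = 0.00774, adjusted p = 0.393 with an estimated correlation). Its called genes with the smallest p were the aldehyde dehydrogenase gene Aldh3a1 and the glutathione transferase genes Gsta2 and Gsta4. Aldh3a1 fell from 385 ± 5.35 to 278 ± 7.35 CPM, and Gsta2 and Gsta4 had log2 fold changes of -2.09 and -0.41. Gsta2 has close relatives that can share reads.

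The remaining called sets were amino acid biosynthesis (camera adjusted p = 0.0330), pyruvate metabolism (0.0411) and fatty acid biosynthesis (0.0426), all higher, and retinol metabolism (0.0342) and xenobiotic metabolism by cytochrome P450 (0.0439), both lower. With an estimated correlation the adjusted p was 0.393 for the first 4 of these and 0.470 for xenobiotic metabolism. The call of fatty acid biosynthesis was lost without vehicle replicate 1 (adjusted p = 0.0598) or palmitate replicate 1 (0.0568). That of retinol metabolism was lost without vehicle replicate 2 (0.0598). The call of xenobiotic metabolism was lost without vehicle replicate 1 (0.0540) or 3 (0.0640) or palmitate replicate 1 (0.0605) or 3 (0.0722). With the replicate number as a block, the adjusted p was 0.0549 for fatty acid biosynthesis, 0.0622 for pyruvate metabolism and 0.0823 for xenobiotic metabolism, so these calls were lost. In the authors' deposited table of gene set enrichment, 3 of 93 sets had an adjusted p under 0.05, namely carbon metabolism, steroid hormone biosynthesis, and fructose and mannose metabolism, and 2 of these were also called by camera. For steroid hormone biosynthesis the authors' normalized enrichment score was 1.79, over 39 genes. Here only the 23 that passed the count filter were tested, so the genes compared are not the same. Of these, 4 were higher and 9 lower. Camera did not call the set (direction Down, adjusted p = 0.727) and fry called it Up (adjusted p = 0.00168). In the authors' deposited table of genes, 5663 had an adjusted p under 0.05, 3102 higher and 2561 lower. Of these, 5592 were also called in the same direction by edgeR, and 0 genes were called by both in opposite directions.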

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

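Thinning to the shallowest library was chosen after the data were seen; the other settings were fixed before. The 7915 called genes became 7883 with median-of-ratios size factors, 8023 with no count filter, 5692 with DESeq2, 7894 with limma-voom and 7509 after thinning, and no gene called in both changed sign. Leaving out each library gave 7260 to 7406. Testing against a fold of 1.2 with glmTreat called 2275, since it asks for more than any difference. Of the 148 named genes with a fitted value, 1924 values under alternatives held 1828 with the same call, 96 that lost it and 0 that changed sign; glmTreat accounted for 54 of the losses.

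The 10 called lists and 11 called metabolic sets both became 0 with an estimated correlation. There limma's camera gave 6 of the 25 tested lists and 8 of the 87 tested sets an unadjusted p under 0.05. Not all of these 8 were among the 11. By fry, which asks another question, 21 and 67 were called. The estimated correlation was below the preset 0.01 for some called sets, such as the PPAR list (-0.0396), the cell cycle list (-0.0140) and carbon metabolism (-0.00619). A larger correlation was therefore not the reason that these lost their call. For the cell cycle list the unadjusted camera p was 9.73e-08 with the preset correlation and 0.00355 with the lower, estimated one. What else differs between the forms of the test was not examined, so these losses do not measure correlation between genes. For others, such as the glycolysis and hypoxia list (0.0481), it was above the preset value. With no count filter, 20 metabolic sets and 9 lists were called; genes below the filter entered the test, and the cause was not tested further. Thinning gave 9 lists and 11 sets, and the replication histones lost their call (adjusted p = 0.0582). Without 1 library the lists called were 10 each time, and the sets 9 to 12. Lists never called changed direction under some settings, and the cause was not tested. The actin list turned to higher with no count filter (adjusted p = 0.868) and without vehicle replicate 2, palmitate replicate 1 or palmitate replicate 3; its adjusted p over the 6 omissions was 0.775 to 1.00. The mesenchymal list turned with no count filter (0.925), and the interferon list without vehicle replicate 1; its adjusted p over the omissions was 0.764 to 0.992.

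Deviations from the group means of same-numbered libraries correlated at -0.00448, 0.00846 and 0.00715 across genes, and not every library correlated best with its own number. No pairing by replicate number was seen. Because libraries of a group varied little beyond counting noise, this cannot tell whether same-numbered samples shared a batch. With the replicate number as a block, 7933 genes, 10 lists and 8 metabolic sets were called. The sets that lost their call were fatty acid biosynthesis (adjusted p = 0.0549), pyruvate metabolism (0.0622) and xenobiotic metabolism by cytochrome P450 (0.0823).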

Other observations

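The test for a shared RNA pool was chosen after its result was seen, and the gene set of the GC content test of mucin genes was settled after those genes' fold changes were seen; the mucin and secretory genes themselves were picked after their values were seen. Beyond the fixed lists, the abundant mucin genes were much lower with palmitate. Muc5ac, a gel-forming mucin gene, was at 686 ± 14.3 CPM with vehicle and 155 ± 6.67 CPM with palmitate (SD, n = 3 each; log2 fold change -2.15), and Muc5b at 393 ± 10.5 and 91.8 ± 0.297 CPM (-2.10). Pigr, the receptor that carries antibodies across epithelium, had a log2 fold change of -1.90, Muc1 of -1.08 and Agr2, which helps to fold mucins, of -1.01, each called by edgeR. Muc2, the main mucin of the colon, was low (2.55 ± 0.484 CPM with vehicle) and was not called (-0.20, adjusted p = 0.323, edgeR). Agr2 and Muc2 are members of the fixed intestinal differentiation list, which was not called by camera. Tph1, an enzyme of serotonin synthesis in enteroendocrine cells, fell by 2.06 on the log2 scale, while Ptgs1, a cyclooxygenase gene of tuft cells among others, rose by 0.39.

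One hypothesis is that a wider secretory program may be lower with palmitate. It was tested on 39 secretory and mucin glycosylation genes whose values had not been looked at. Of 29 tested, 17 were lower, 8 higher and 4 not called, with a median log2 fold change of -0.15, and the list ranked lower than other genes by camera (p = 0.0129), though not with an estimated correlation (p = 0.111). Ern2 (-1.88), Bcas1 (-1.59) and Creb3l4 (-1.43) were lower, but Sytl4 (2.09), Gcnt1 (0.58) and Hid1 (0.42) were higher, so the hypothesis rests on part of the list. Sytl4 was at only 0.129 ± 0.0345 CPM with vehicle and 0.562 ± 0.0664 CPM with palmitate, so its fold change is uncertain. The authors' set for mucin type O-glycan biosynthesis, which shares members with the list, was not lower: 9 of 19 tested genes were higher and 7 lower, with camera direction Up (adjusted p = 0.836). GC content or length bias was argued against: a prediction that named 6 genes had not recorded which, so the test used all 17 mucin and secretory genes examined by then, of which 11 were tested and 10 had a GC content and length; their median was -1.54 before and -1.54 after the trend was removed. Both candidate choices of 6 gave -1.97 after it. The trend held 0.633% of the variance of the log2 fold change over all genes, so removing it could move these medians only little.

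Many genes were called with small folds. Greater depth of the palmitate libraries was argued against as the cause, since thinning all libraries to the shallowest total left 7509 genes, 94.9% of the count. What stays open is whether the 3 libraries of a group came from 1 culture or RNA pool: the variance between 2 libraries was at most 1.38 times that of counting alone, which cannot be told apart from separate cultures that vary little, because the labels do not give their origin. If so, differences between single cultures may be counted with those of palmitate.

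The cell cycle list was called higher with palmitate by camera with a preset correlation, but not with an estimated correlation (adjusted p = 0.0670). Its p on the test statistics with the preset correlation was 1.47e-09 before and 1.75e-09 after their trend with GC content and length was removed, and that trend held 0.226% of the variance. After thinning, its adjusted p with the preset correlation was 2.70e-06. Both values were little moved, which argues against GC content, length and depth as its cause. A response to palmitate is a candidate explanation, as is a difference between cultures, and neither was tested. For the PPAR list the p was 4.76e-14 before and 8.80e-14 after the same correction.

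Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split called 7915 genes and the highest other 0; it called 11 metabolic sets and the highest other 0. It called 10 fixed lists, while 6 of the 9 splits that mixed the groups called at least 1 list and at most 5. Each mixed split had unequal numbers of palmitate libraries on its sides, so part of the difference between treatments remained. Lists called there are therefore not necessarily false calls. Mixing also put that difference within the groups, which raises their spread, so the low counts of the other splits were partly fixed in advance. In each of the 3 cases 1 split, the real one, reached the real count.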
